A study of Mus musculus with 4 samples.

How the data were processed

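RNA was measured by sequencing in 4 mouse testis libraries of the BALB/C strain, with 1 library at each of embryonic day 14 (E14), embryonic day 18 (E18), 3 weeks after birth and 6 months after birth. Per the labels' protocols, the tissue RNA was bought from a supplier, ribosomal RNA was depleted, spike-in RNA was added, polyadenylated RNA was isolated, and libraries were made with a directional kit. The labels differ on the selection: the sample description and the design text name ribosomal RNA depletion alone, while the molecule field and the protocol also name polyadenylated RNA. Each deposited file gives RPKM, which are reads scaled to the length of the gene model and to the total of reads, for 112302 entries named by upper-case symbol or database identifier. TopHat2 and the mouse build mm10 are named per the submitters' processing notes. The counter, the annotation, and the treatment of strand, multiply mapped reads and overlapping genes are not given in the sources used here.

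Entries overlap, since older and newer names of a gene can both be present and since many identifiers lie inside other genes, so counts of entries are not counts of independent genes. Values of near-identical copies (the alpha globins Hba-a1 and Hba-a2, the adult beta globins, ribosomal protein genes and Gapdh with their many pseudogenes, Rprl2 and Rprl3, and histone genes) are uncertain because reads may have been split or shared between copies. The same holds for genes with an antisense or overlapping partner. No spike-in entry was matched by name, so the planned spike-in scaling was not run.

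The reads behind the deposited RPKM were recovered from the steps between low values. For single-exon genes, the most frequent value of RPKM times annotated length gave the RPKM denominator, which was 38903334 reads at E14, 34228140 at E18, 33952471 at 3 weeks and 35801602 at 6 months. Whole reads and 1 shared model length were then found for 99.9966% of the 59564 entries above 0 in all 4 libraries, at a relative tolerance of 1e-09 and lengths up to 200000 bases. Of 7962 single-exon annotated genes, 74.1% had a recovered length equal to the annotated one. For 79.1% the annotated length was a whole multiple of the recovered one. The recovered reads are the smallest whole numbers that give the values, so a common factor may be lost and an interval may then be too wide. At these depths, 3 reads in a gene model of 1 kb correspond to an RPKM of 0.0771 at E14, 0.0876 at E18, 0.0884 at 3 weeks and 0.0838 at 6 months. Exact Poisson intervals of levels and exact Clopper-Pearson intervals of ratios, both at 95%, cover counting error only, since reads copied by PCR are not independent molecules.

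Differences were computed as log2(RPKM + 1) at the later stage minus that at the earlier stage, with a pseudocount of 1, which understates the change of low genes. Entries of at least 1 RPKM in at least 1 library entered (42964 entries), and a difference of at least 1 in size, 2-fold on that scale, was called higher or lower. The 3 comparisons were those of adjacent stages. With 1 library per stage there was no replicate check, so no p-value was computed, and "higher" and "lower" describe these libraries. For each of 29 gene lists, the median difference was placed among those of 10000 random lists of the same size matched on mean log2(RPKM + 1) in 10 classes, as a description of these libraries. The random lists were drawn from all 42964 measured entries, of which 12960 were established symbols. Lists with fewer than 5 measured members have values only. A list's median has an exact binomial 95% interval over its genes, which are not replicates.

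The genes named in each comparison were set by a rule: the 6 largest differences in each direction among established symbols with a mean RPKM of at least 5, up to 2 members in each direction of each list described, Piwil1, Piwil2, Piwil4, Ago1 to Ago4 and Dicer1, and the 3 largest leads per stage. Predicted and unnamed gene models were left out. Forms of database identifier that the rule did not foresee were also treated as unnamed, a choice made after the data were seen. Markers of muscle, cartilage, liver, neurons, epidermis, kidney, bladder, the Y chromosome and the inactive X chromosome were likewise named after values had been seen. The 29 gene lists and the rest of the rule were set before the data were examined, and tests and alternatives chosen later are named as such where they are given. Chromosome, position and gene type came from GENCODE vM21 on GRCm38, the assembly also called mm10, by symbol.

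The alternatives were a pseudocount of 0.1, no filter, a minimum RPKM of 5, a size limit of 4-fold, established symbols alone, and rescaling to an equal sum, by the median of ratios, or over ribosomal protein genes. Chosen after seeing the data were rescaling over protein-coding genes, protein-coding genes alone, and leaving E14 out of the filter or out of the ranking of stages. The procedure was tested on simulated data for E18 against E14 with 98240 entries, of which 24431 passed the filter: 95% of 200 genes changed 4-fold passed the size limit, and 156 unchanged entries (0.644% of those past the filter) passed it by counting error. The changed genes were drawn from entries with a mean level above the minimum of the filter. The 95% does not cover entries near that minimum. Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.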

Results

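RNA labelled as mouse testis was profiled in 4 libraries, labelled E14, E18, 3 weeks and 6 months. The series' title concerns endonucleolytic cleavage of transcripts and the small RNAs that induce it, and these libraries give transcript levels at 4 stages. Reads behind the RPKM values ranged from 33952471 at 3 weeks to 38903334 at E14. RPKM of at least 1 was reached by 22135 entries at E14, 23658 at E18, 33267 at 3 weeks and 29669 at 6 months. Across the 42964 measured entries, which are not independent replicates, Pearson's r of log2(RPKM + 1) was 0.956 between E14 and E18 and 0.776 between 3 weeks and 6 months. Between a fetal and a postnatal library it lay between 0.272 and 0.323.

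Between E14 and E18, Sertoli cell, Leydig cell and contractile genes were higher. Of 19 measured Sertoli cell genes, 14 were at least 2-fold higher at E18 (9 under ribosomal protein scaling and 8 at 4-fold) and 0 were lower, led by Defb19, a defensin (0.457 RPKM at E14 and 35.6 at E18, log2 difference 4.65), and Cst9, a cystatin (0.486 and 27.7, log2 difference 4.27). Among 14 steroid synthesis and Leydig cell genes, 10 were higher (6 at 4-fold) and 0 lower, with the largest differences for Insl3, the hormone of testicular descent (0.864 and 33.7 RPKM), and Cyp17a1, an enzyme of androgen synthesis (1.38 and 37.8 RPKM). Contractile genes of peritubular and smooth muscle were higher in 8 of 10 cases, with Actg2 at 34.0 and 226 RPKM and Tagln at 50.03 and 249 RPKM. The medians of these 3 lists, 1.34, 1.73 and 1.36, each lay above those of all 10000 matched random lists. Endothelial and macrophage genes had 0 of 9 and 0 of 10 members past 2-fold. In the same comparison the summed RPKM of bladder urothelium markers was 8.57 and 41.3 and that of kidney tubule markers 1.12 and 33.0, while that of cartilage markers was 97.8 and 1.60, of skeletal muscle 211 and 29.0, of liver 331 and 81.5 and of neurons 56.3 and 9.24. Markers of other tissues thus differed in both directions, so changes within the testis were not separated from differences in tissue make-up.

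Genes of the piRNA pathway, meiosis and spermatids had low list medians in both fetal libraries, and some were higher at E18. Testis markers as a set had a median log2(RPKM + 1) of 0.34 at E14 and 3.16 at E18. A lower share of testis RNA in the E14 library was thus not separated from change within germ cells. In the PIWI-piRNA pathway, 4 of 21 measured genes were at least 2-fold higher and 0 lower (median 0.42), a count that was 14 with a pseudocount of 0.1 and 1 at 4-fold, led by Mael (0.366 and 8.43 RPKM) and Fkbp6 (0.132 and 2.75 RPKM). Piwil2 stood at 0.0471 RPKM at E14 and 2.05 at E18, while Piwil4, which acts in fetal germ cells, stood at 0.0430 and 0.483 and Piwil1 at 0.0254 and 0.152. Among 26 meiotic prophase genes, 3 were higher, with Tex15 at 0.601 and 2.55 RPKM and Sycp3 at 0.651 and 2.496. Of the 9 measured spermatogonial genes, with list medians of 1.49 and 1.46 on the log2 scale, 1 was higher, Sohlh1 (0.0399 and 1.75 RPKM). The fetal germ cell list had 3 measured genes: Pou5f1 (0.0678 and 1.23 RPKM), Dnmt3l (0.0946 and 1.21 RPKM) and Sox2 (1.16 and 0.297 RPKM). Round and elongating spermatid genes had 0 of 20 and 0 of 21 members past 2-fold.

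The largest named decreases to E18 included genes of other tissues. The embryonic beta globin Hbb-y had 92.5 RPKM at E14 and 0.354 at E18 (log2 difference -6.11), and the cartilage collagens Col9a1 (25.9 and 0.251) and Col2a1 (20.4 and 0.145), the fast muscle light chain Mylpf (146 and 10.7) and the fetal liver protein Afp (93.9 and 7.66) followed. Of 10 erythroid genes 3 were lower, with Slc4a1 at 23.7 and 1.63 RPKM. Imprinted growth genes had 3 of 13 members lower, led by Peg10 (19.9 and 4.93) and Cdkn1c (62.9 and 17.4). Xist, the RNA of the inactive X chromosome, had 12.7 RPKM at E14 and 0.124 at E18, and the annotated fragment of an exon was among the 6 largest decreases. The Y-linked gene Ddx3y had 1.47 RPKM at E14 and 4.70 at E18. Kidney tubule markers went the other way, with Slc34a1 at 0.585 and 11.98 RPKM, and so did the bladder marker Upk1a, at 2.85 and 12.9 RPKM.

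**Figure D1:**
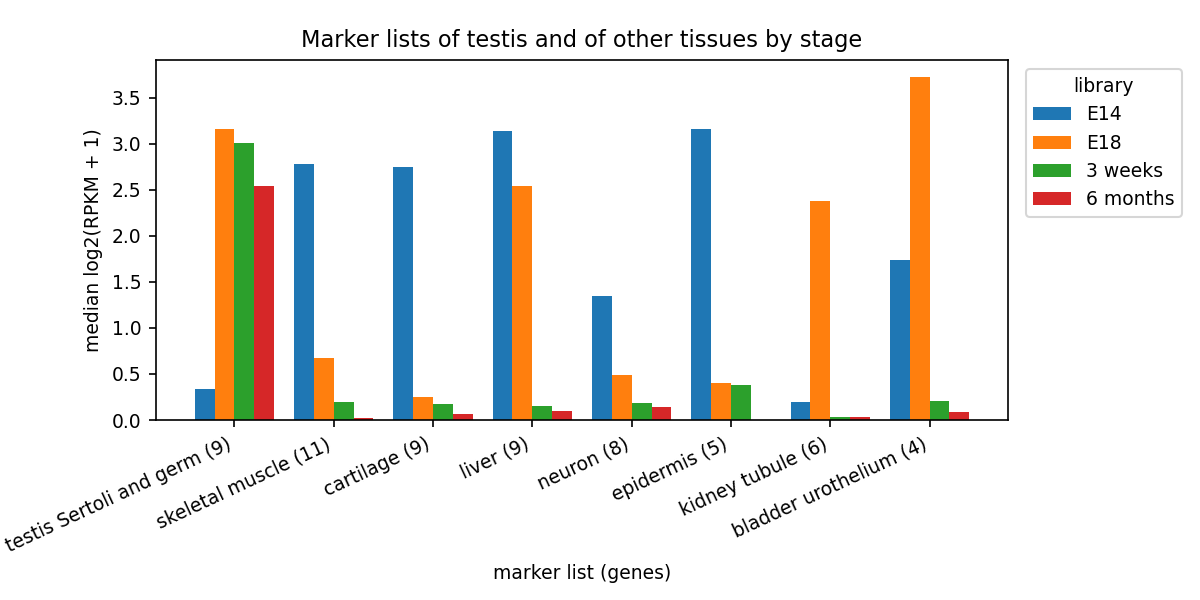
Bars give the median log2(RPKM + 1) of marker lists (x axis, number of genes in parentheses) in the 4 libraries, 1 per stage, with no error bars because there are no replicates. The testis list stood at 0.34 at E14 against 3.16 at E18, while the cartilage list stood at 2.75 against 0.25.

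In the retinoic acid list, Aldh1a1, which makes retinoic acid, was higher at E18 (1.77 and 49.4 RPKM), while the binding proteins Crabp1 (24.4 and 4.01) and Crabp2 (9.33 and 2.59) were lower. Stromal genes were higher in 5 of 14 cases, led by Dcn and Tcf21 (log2 differences 1.75 and 1.70), and Cdh16 was the member past 2-fold among 7 mesonephros genes (1.70 and 16.9 RPKM). Argonaute and miRNA pathway genes had 0 of 13 members past 2-fold: Ago1 stood at 3.18 and 3.36 RPKM, Ago2 at 4.71 and 2.88, Ago3 at 0.661 and 0.693, Ago4 at 0.400 and 0.248, and Dicer1 at 1.28 and 1.07. The 5'-3' decay, exosome and nonsense-mediated decay lists also had 0 members past 2-fold, of 27, 16 and 13. Rprl2, an RNase P RNA copy, was the largest named increase (4.197 and 143 RPKM), with uncertain sharing of reads with related copies.

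Over all entries, 934 were at least 2-fold higher at E18 and 574 lower (61.9% higher among those past the limit). Rescaling by the median of ratios gave 797 and 750 (51.5% higher) and rescaling over ribosomal protein genes 417 and 446 (48.3% higher). Among established symbols the counts were 448 and 230. Leaving E14 out of the filter left 322 lower entries. The 34 named genes past 2-fold all had a counting interval of the ratio that excluded 1. Genes picked for large differences in the same data pass such a check readily, here and in the later comparisons.

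Between E18 and 3 weeks, genes of meiosis and the piRNA pathway were higher. Of 26 meiotic prophase genes, 25 were at least 2-fold higher at 3 weeks and 0 lower (median 3.31, interval 2.04 to 4.11), led by Syce1 of the synaptonemal complex (0.979 and 128 RPKM) and the chaperone Hspa2 (1.66 and 168 RPKM). The PIWI-piRNA pathway had 20 of 21 members higher (median 2.68), with Piwil1 at 0.152 and 60.3 RPKM and Mael at 8.43 and 264 RPKM. Piwil2 stood at 2.05 and 17.2 RPKM and Piwil4 at 0.483 and 0.104. Spermatid genes were higher in 15 of 20 cases for the round spermatid list, led by Dkkl1 (0.162 and 84.0 RPKM) and Spata16 (0 and 37.0 RPKM), and in 13 of 21 for the elongating spermatid list, whose largest differences were Meig1 (0.265 and 349 RPKM) and Smcp (0.0986 and 6.39 RPKM).

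**Figure D2:**
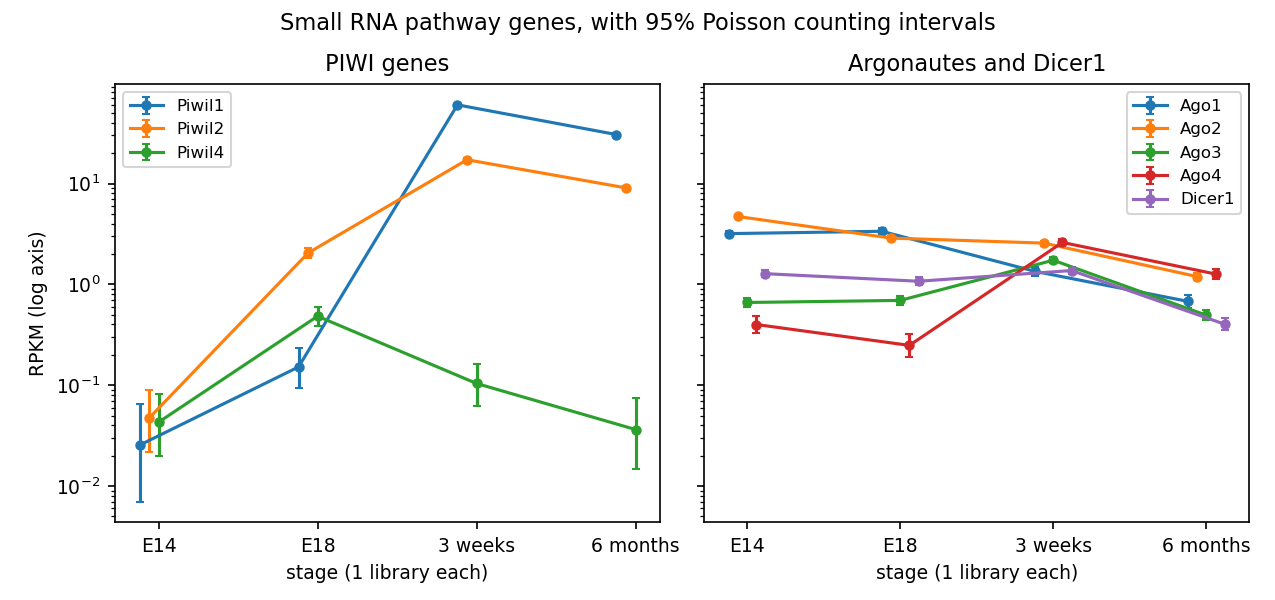
Points give RPKM on a log axis at each stage, 1 library each, for PIWI genes (left) and Argonautes with Dicer1 (right), and bars give 95% Poisson intervals, which cover counting error only. Piwil1 stood at 0.152 RPKM at E18 and 60.3 at 3 weeks, while Ago2 stood at 2.88 and 2.56.

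The largest named increases were those of the fatty acid binding protein Fabp9 (0.407 and 429.7 RPKM), Meig1, Spata4 (0.193 and 268 RPKM), Tcte3 (0.143 and 224), the germ cell lactate dehydrogenase Ldhc (0.259 and 227) and Rsph1 (0.627 and 266). Testis-specific isozymes were higher in 9 of 12 cases and lower in 0, led by Ldhc and Cox7b2 (0.269 and 101 RPKM). Their somatic counterparts were lower in 9 of 13 cases and higher in 0, with Cox8a at 62.7 and 11.7 RPKM and Pgk1 at 10.4 and 1.40. Spermatogonial genes had 4 of 9 members higher, led by Dmrtb1 (0.196 and 60.5 RPKM) and Stra8, which is induced by retinoic acid (0.0324 and 4.80 RPKM).

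Stromal, contractile, endothelial, imprinted and erythroid genes were lower at 3 weeks. Stromal genes were lower in 13 of 14 cases (median -2.11), or 7 under ribosomal protein scaling, led by Lum (38.8 and 3.11 RPKM) and Col6a1 (50.7 and 6.09). Of 10 contractile genes 9 were lower, with Actg2 at 226 and 2.73 RPKM and Tagln at 249 and 10.4, and of 9 endothelial genes 8 were lower, with Cdh5 at 22.5 and 2.62. Imprinted growth genes were lower in 12 of 13 cases (median -3.06), with H19 at 101 and 1.15 RPKM and Mest at 76.3 and 1.16, and 8 of 10 erythroid genes were lower. Cardiac actin Actc1 (66.4 and 0.182 RPKM) and the histone Hist1h1b (88.4 and 1.27) were also among the largest decreases, beside H19 and its annotated fragments. Mesonephros genes were lower in 3 of 7 cases, led by Cdh16 (16.9 and 0.870), and in the same comparison the kidney marker Slc34a1 had 11.98 RPKM at E18 and 0 at 3 weeks. The summed RPKM of markers of other tissues was also lower, at 41.3 and 0.587 for bladder urothelium, 81.5 and 2.20 for liver and 29.0 and 1.92 for skeletal muscle. The decreases of stromal, contractile and endothelial genes were thus not separated from a difference in tissue other than testis.

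Sertoli cell genes went both ways, with 7 of 19 higher and 5 lower. Tsx (0.109 and 5.20 RPKM) and Rhox8 (1.11 and 9.50) had the largest increases, and Amh, the anti-Müllerian hormone (11.4 and 0.478), and Krt18 were lower, with a log2 difference of -3.07 for Amh. Leydig cell genes had 6 of 14 members lower, led by Hsd17b3 (12.5 and 1.35 RPKM) and Cyp11a1 (29.5 and 9.43), and 1 higher, Hsd3b6 (0.324 and 5.57). Retinoic acid genes had 3 of 15 members higher and 5 lower. Macrophage genes had 1 of 10 higher, Fcgr3 (1.024 and 8.12 RPKM). Proliferation genes had 1 of 19 higher, Bub1 (3.06 and 16.2), and 3 lower, led by Ccna2 (11.7 and 3.44).

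Genes of RNA decay were higher in part. In this comparison 32.0% of all entries and 22.5% of established symbols were at least 2-fold higher. The nonsense-mediated decay and endonuclease list had 7 of 13 members higher and 0 lower (median 1.14), led by Upf3a (0.449 and 5.56 RPKM) and Upf2 (1.38 and 6.48). For the 5'-3' decay list, 7 of 27 were higher, led by the deadenylase scaffold Cnot1 (9.80 and 53.9) and Lsm2 (1.32 and 8.95), and for the exosome list 3 of 16, led by Dis3l (2.39 and 40.5). The medians of these lists lay above 9173, 3623 and 5700 of 10000 matched random lists. Argonaute and miRNA pathway genes had 3 of 13 members higher, led by Ago4 (0.248 and 2.60 RPKM) and Tarbp2 (1.53 and 4.86). Not past 2-fold on the log2(RPKM + 1) scale were Ago1 at 3.36 and 1.35 RPKM, Ago2 at 2.88 and 2.56, Ago3 at 0.693 and 1.73, and Dicer1 at 1.07 and 1.37. By RPKM without the pseudocount, Ago1 was lower and Ago3 higher by more than 2-fold. DNA methylation genes had 1 of 12 higher, Setdb1.

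Mitochondrial protein genes were higher in 10 of 13 cases, with mt-Nd4l at 61.4 and 293 RPKM, and took 0.373% of reads at E18 and 0.952% at 3 weeks. Mitochondrial ribosomal RNA took 6.85% and 11.4% of reads. Ribosomal protein genes were lower in 21 of 28 cases (median -1.28), led by Rps4x (35.3 and 3.45 RPKM), a direction that is set to about 0 (0.12) when libraries are rescaled over those genes. The epididymis gene Crisp1 had 0.206 RPKM at E18 and 41.5 at 3 weeks, and Adam7 had 0.0560 and 2.38. Usual reference genes had 3 of 16 members higher and 5 lower.

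Over all entries, 13742 were at least 2-fold higher at 3 weeks and 4532 lower (75.2% higher among those past the limit), against 2915 and 1862 among established symbols (61.0% higher). Rescaling over ribosomal protein genes gave 26117 and 783 (97.1% higher) and rescaling over protein-coding genes, chosen after seeing the data, 11519 and 6536 (63.8% higher), with median shifts over all entries of 0.82 and -0.22. The 67 named genes past 2-fold all had a counting interval that excluded 1. Short entries with names that begin with DQ reached 1 RPKM in 118 cases at E18 and 4116 at 3 weeks.

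**Figure D3:**
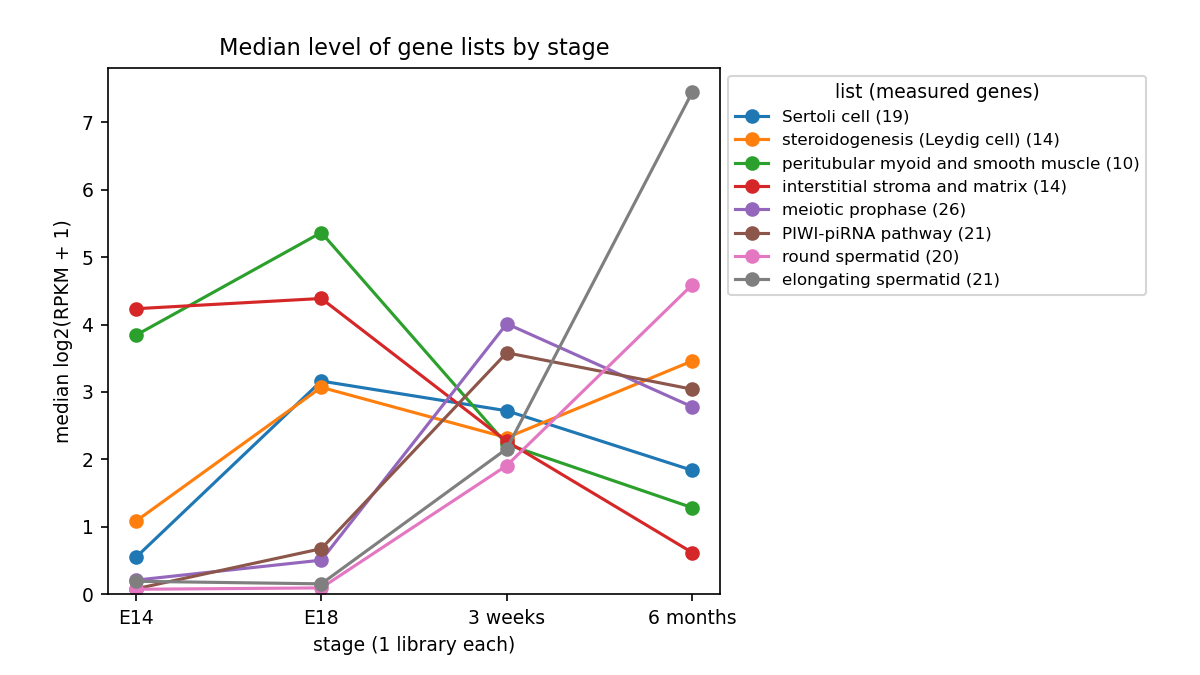
Lines join the median log2(RPKM + 1) of the measured members of 8 gene lists (number in parentheses) across the 4 stages, 1 library each, without error bars because there are no replicates. The meiotic prophase list stood highest at 3 weeks (4.01) and the elongating spermatid list at 6 months (7.45).

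Between 3 weeks and 6 months, genes of late spermatids were higher. Of 21 elongating spermatid genes, 20 were at least 2-fold higher at 6 months and 0 lower (median 5.23, interval 3.82 to 5.87), led by the protamines Prm2 (0.760 and 1528 RPKM, log2 difference 9.76) and Prm1 (0.573 and 905 RPKM). The transition proteins Tnp1 (3.46 and 2299.6 RPKM) and Tnp2 (0.964 and 937) followed. Protamine and transition protein genes together had 114 reads at 3 weeks and 105963 at 6 months. Round spermatid genes were higher in 12 of 20 cases and lower in 0, led by Spem1 (0.169 and 172 RPKM) and the kinase Tssk6 (0.221 and 100.2 RPKM), and Cabs1 was also among the largest increases (0.411 and 139 RPKM).

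Meiotic genes were lower at 6 months in 11 of 26 cases and higher in 2 (median -0.89), with Sycp2 at 65.9 and 10.7 RPKM and Meiob at 20.1 and 3.97, while Rec8 was higher (1.94 and 7.03). In the PIWI-piRNA pathway 5 of 21 members were lower, led by Tdrkh (7.55 and 2.26) and Tdrd1 (20.04 and 7.23), and 1 was higher, Gtsf1 (7.48 and 24.7). Piwil1 stood at 60.3 and 30.6 RPKM, Piwil2 at 17.2 and 9.06, and Piwil4 at 0.104 and 0.0363. Ago1 had 1.35 and 0.678 RPKM, Ago2 2.56 and 1.19, Ago3 1.73 and 0.494, Ago4 2.60 and 1.27, and Dicer1 1.37 and 0.402. On the log2(RPKM + 1) scale 1 of 13 genes of their list was lower by at least 2-fold, Tnrc6a (4.11 and 1.43). By RPKM without the pseudocount, Ago2, Ago3, Ago4 and Dicer1 were also lower by more than 2-fold. The 5'-3' decay list had 2 of 27 members lower, Lsm3 and Ddx6, the nonsense-mediated decay list 1 of 13, Upf2, and the exosome list 1 of 16 higher, Exosc5 (5.41 and 12.1).

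Leydig cell genes were higher at 6 months in 7 of 14 cases, led by Insl3 (19.6 and 357 RPKM) and Cyp17a1 (23.6 and 119.8), with 1 lower, Srd5a1 (2.25 and 0.243), the enzyme that makes dihydrotestosterone. Stromal genes were lower in 11 of 14 cases (4 at 4-fold) and higher in 0, led by Col3a1 (14.3 and 0.773) and Col1a1 (5.52 and 0.230), and elastin, Eln, was among the largest decreases (13.6 and 0.473). Contractile genes had 6 of 10 members lower, led by Acta2 (24.5 and 6.72), and 1 higher, Actg2 (2.73 and 57.5). Sertoli cell genes had 3 of 19 lower, led by Rhox8 (9.50 and 1.67). Endothelial and macrophage genes had 0 of 9 and 0 of 10 members past 2-fold, and proliferation genes 4 of 19 lower, led by Mki67 (4.28 and 0.785).

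Mitochondrial protein genes were lower in 13 of 13 cases, with mt-Atp8 at 986 and 142 RPKM, and took 0.952% of reads at 3 weeks and 0.242% at 6 months. Crisp1 had 41.5 RPKM at 3 weeks and 0.0197 at 6 months, and the RNase P RNA copies Rprl3 (3283 and 11.4 RPKM) and Rprl2 (503 and 3.14), Spink8 (22.0 and 0.739) and Fabp4 (24.4 and 1.70) were also lower. Testis-specific isozymes had 4 of 12 higher, led by Gapdhs (2.73 and 162 RPKM), and 2 lower. Somatic isozymes had 1 of 13 higher, Aldoa, and 3 lower, ribosomal protein genes 1 of 28 higher and 4 lower, and imprinted genes 1 of 13 lower. The ovary list had 2 measured genes, Fst (0.201 and 0.0952 RPKM) and Nlrp5 (0.374 and 1.73).

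Over all entries, 4182 were at least 2-fold higher at 6 months and 6062 lower (40.8% higher among those past the limit), against 1081 and 1045 among established symbols (50.9% higher). The split depended on the setting: a size limit of 4-fold gave 1376 and 775 (64.0% higher), the median of ratios gave 6100 and 2710 (69.2% higher), ribosomal protein scaling 7070 and 4393 (61.7% higher) and rescaling over protein-coding genes, chosen after seeing the data, 3193 and 7597 (29.6% higher), and the median shifts over all entries under these 3 rescalings were 0.31, 0.32 and -0.14. The 59 named genes past 2-fold all had a counting interval that excluded 1. Short entries with names that begin with DQ made up 2141 of the 6062 lower entries and 34 of the 4182 higher ones.

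The median difference of X-linked genes was below that of autosomal genes in the 2 comparisons that include a postnatal library. The median difference of 884 X-linked genes was 0.04 at 3 weeks against E18 and that of 16388 autosomal genes 0.24, with 1 of 10000 matched autosomal sets below the X median. The gap between these medians was -0.0255 with no filter and -0.77 with a minimum RPKM of 5. At 6 months against 3 weeks the medians were -0.29 and -0.21, with 0 of 10000 sets below and a gap of -0.0211 with no filter, and at E18 against E14 they were 0.06 and 0.07, with 9431 sets below. At 3 weeks, 17.4% of X-linked and 24.6% of autosomal genes were at least 2-fold higher than at E18, while at 6 months 15.4% and 10.2% were at least 2-fold higher than at 3 weeks and 13.9% and 8.88% lower.

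By stage of highest level, 18862 entries peaked at 3 weeks, 10482 at 6 months, 8104 at E18 and 5516 at E14. A lead of at least 2-fold over each other stage was held by 3898, 3605, 356 and 411. The order of 3 weeks and 6 months depended on the setting: under the median of ratios 13705 entries peaked at 3 weeks and 14034 at 6 months, with leads of 1912 and 4913, and leads numbered 411 and 920 among established symbols. Of the entries that peaked at 3 weeks, 3698 were short entries with names that begin with DQ. The largest leads among named genes were those of Hbb-y, the Xist exon fragment and Col9a1 at E14, Adh1 (30.6 RPKM), Tagln and the pseudogene Rpl21-ps8 at E18, Crisp1, Rprl3 and Spink8 at 3 weeks, and Prm2, Prm1 and Tnp1 at 6 months. Without E14, 3733 entries held such a lead at E18.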

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

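The settings named as chosen after seeing the data were rescaling over protein-coding genes, protein-coding genes alone and leaving out E14. Under all settings run, 0 of 300 differences of named genes changed sign after a call. Named genes were picked mainly for large differences in the same data, so this count does not measure how stable other genes are. Of 765 list medians, 1 changed sign after a call, the ribosomal protein median at 3 weeks against E18. It was 0.12 under scaling over those genes, by that scaling's construction. The 765 also hold medians without a call, such as that of the Argonaute list at E18 against E14 (-0.058). A change of sign in those was not counted, so 1 of 765 does not measure how stable the list medians are. The spike-in scaling was not run. Depth limits values under the level of 3 reads. No paired analysis was possible because each stage has 1 library. Where no construction (fewer entries, a larger limit, a smaller pseudocount) accounts for a move, the cause was not tested.

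Counts are given as higher and lower for E18 against E14, then 3 weeks against E18, then 6 months against 3 weeks. Established symbols alone gave 448 and 230, 2915 and 1862, 1081 and 1045. Protein-coding genes alone gave 448 and 207, 3047 and 1670, 1204 and 995. A size limit of 4-fold gave 118 and 90, 6922 and 852, 1376 and 775. With a pseudocount of 0.1, 3204 were higher and 1768 lower at E18, 7687 lower at 3 weeks and 13337 lower at 6 months. With a minimum RPKM of 5, 511 were higher and 283 lower at E18, 2652 lower at 3 weeks and 2367 higher at 6 months. Ribosomal protein scaling gave 417 higher at E18, 26117 higher and 783 lower at 3 weeks, and 7070 higher at 6 months. The median of ratios gave 2710 lower at 6 months, and the filter without E14 gave 322 lower at E18.

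Leads of at least 2-fold at E14, E18, 3 weeks and 6 months numbered 178, 209, 411 and 920 for established symbols, 161, 203, 422 and 1048 for protein-coding genes, and 68, 29, 682 and 1254 at 4-fold. A pseudocount of 0.1 gave 856 at E14, 831 at E18 and 6670 at 3 weeks. A minimum RPKM of 5 gave 221 at E14, 191 at E18 and 2042 at 6 months. Ribosomal protein scaling gave 200 at E14, 70 at E18 and 6613 at 6 months. The median of ratios gave 1912 at 3 weeks, the filter without E14 gave 205 at E14, and ranking without E14 gave 3733 at E18.

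The X minus autosomal median at 3 weeks against E18 was -0.57 for established symbols, -0.77 with a minimum RPKM of 5, -0.0255 with no filter, -0.41 for protein-coding genes, -0.33 with a pseudocount of 0.1 and -0.41 under ribosomal protein scaling. At 6 months against 3 weeks it was -0.18, -0.0211, -0.25 and -0.17 for established symbols, no filter, the pseudocount of 0.1 and ribosomal protein scaling. At E18 against E14 it was 0.0260 for established symbols and 0.0169 with the pseudocount of 0.1.

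At E18 against E14, PIWI-piRNA genes higher numbered 14 with a pseudocount of 0.1 and 1 at 4-fold, Sertoli cell genes 9 under ribosomal protein scaling and 8 at 4-fold, and Leydig cell genes 6 at 4-fold. Stromal genes lower numbered 7 at 3 weeks under ribosomal protein scaling and 4 at 6 months at 4-fold.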

Other observations

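The tests of sequencing depth and of Xist for the library labelled E14, that of the Crisp3 level, that of expression level for X-linked genes, the counts without a filter for the E14 marker lists, and the check of how X-linked genes pass the filter were chosen after the result was seen. The test of other tissue in that library replaced an earlier one on the same tissues, whose lists and bounds were written after values were seen and in which neuron markers (median 0.91 higher at E14 than at E18) and posterior Hox genes (0.64) stayed under 2-fold; a test of age at E14, which could reach 1 label only, was run and dropped. A test of scaling for X-linked genes was also dropped, on the assumption that a factor per library nearly cancels, which does not hold: the X minus autosomal median at 3 weeks against E18 was -0.16 under the median of ratios and -0.41 under ribosomal protein scaling, the range of 4 rescalings. Entries named by GenBank-style numbers that begin with DQ numbered 4194, with a median recovered length of 38 bases among the 3277 with 20 or more reads. At such lengths 1 RPKM takes fewer reads than in a gene model of 1 kb. RPKM of at least 1 was reached by 81 of these entries at E14, 118 at E18, 4116 at 3 weeks and 3996 at 6 months. They held 26722 reads at E14, 33453 at E18, 224260 at 3 weeks and 98447 at 6 months, and 2141 were at least 2-fold lower and 34 higher at 6 months than at 3 weeks. Reads may be shared with longer entries that overlap them, for which no test was made, and the scaling of the libraries bears on the counts as for all entries, where the median of ratios gave 2710 lower.

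RNAs made without a poly(A) tail were abundant. Rpph1, the RNA of RNase P, had 6588 RPKM at E14, 7655 at E18, 3444 at 3 weeks and 2747 at 6 months, and 7SK RNA took 1.28%, 1.58%, 0.723% and 1.11% of reads. The replication-dependent histone Hist1h3b had 234 RPKM at E14, 160.2 at E18, 7.08 at 3 weeks and 8.11 at 6 months.

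The library labelled E14 had low testis markers and high markers of other tissues. E14 had 1.14 times the reads of E18, but RPKM is already scaled to the total of reads, so this ratio decides nothing about the marker levels. Xist at 12.7 RPKM, against 0.158 or less in the others, argues against male tissue alone. Other embryonic tissue, some of it female, may be in that library: 5 of 5 further marker lists of muscle, cartilage, liver, neurons and epidermis, written before their values were seen, had a median at least 2-fold higher at E14 than at E18, with 25 of 33 measured genes higher and 1 lower, Lgals7 (2.41 and 8.19 RPKM), which is 1 of only 3 in the epidermis list, and 8 of the 33 reached 1 RPKM in a postnatal library. The filter bears on this, since 14 of the 33 entered by E14 alone and 0 by E18 alone: without a filter 2 of 5 lists were past 2-fold and 46 of 55 genes were higher and 4 lower beyond counting error, and of the 14 genes with at least 1 RPKM at E18, 9 were 2-fold higher at E14 and 1 lower. Age stays open for the testis markers: the test of age could reach 1 label only and was dropped, and E14 has 1 library. Kidney tubule and bladder urothelium markers were highest in the E18 library, with summed RPKM of 33.0 and 41.3. Other tissue may therefore be in the E18 library too, which was not tested.

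Crisp1, a gene of the epididymis, stood at 41.5 RPKM in the 3 week library. Reads shared among Crisp genes are argued against by Crisp2, which was 0.66 higher on the log2 scale at 6 months than at 3 weeks, and for Crisp3, which was lower as sharing would need (1.27 and 0.0394 RPKM), by its level at 3 weeks, with 61 reads against 1995 of Crisp1. Epididymal tissue in the 3 week library could not be told from other sources: 41.7% of 12 further epididymis genes (5 genes: Ces5a, Lcn12, Spink10, Wfdc9 and Wfdc13) were highest at 3 weeks beyond counting error, between the bounds set in advance, and Gpx5, abundant in epididymis, had 0.0528 RPKM. Of the 4 measured genes of the first epididymis list, Crisp1 and Adam7 (2.38 RPKM) were highest at 3 weeks. Rnase10 (2.28 RPKM) and Defb21 (1.11 RPKM) were highest at 6 months. Among members under 1 RPKM in all libraries, Lcn5 had 21 reads at 3 weeks and Spag11a 11, with 1 or fewer in each other library. Lcn8, Lcn9, Cst11 and Defb20 had 3 or fewer reads in every library, and Spag11b had 0 RPKM throughout. Age was not tested as an explanation.

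The median difference of X-linked genes was below that of autosomal genes at 3 weeks against E18. A difference in mean level alone is argued against, since 1 of 10000 matched autosomal sets had a median below that of X. The matching used the mean over all 4 libraries, which includes the 3 week values. Level still bears on the size of the gap, which was -0.0255 with no filter and -0.77 with a minimum RPKM of 5. A smaller share of somatic cells stays open: of genes under 1 RPKM at E18, 33.5% on X (interval 28.8 to 38.5) and 44.6% on autosomes (43.3 to 46.0) were at least 2-fold higher at 3 weeks, as the bound set in advance against it asked, but 38.7% of these genes on X and 20.3% on autosomes had entered by 6 months alone, so the filter bears on the shares and the bound does not decide. Silencing of the X chromosome in meiosis may contribute, as a hypothesis with no test of its own here, and reads shared between multicopy X-linked families were not tested.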
